A study of Mus musculus with 4 samples.

How the data were processed

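Total RNA of 4 tumour-bearing eyes of C57BL/6 mice was measured on Affymetrix mouse arrays with 45101 probe sets, with 2 arrays from intact and 2 from splenectomized mice. Per the labels, biotinylated RNA was prepared with a 3'-IVT Express kit. The deposited values are linear signal intensities and detection calls (Present or Absent) for each probe set, made by the authors with GCOS 1.4 and MAS5. The scaling target is not given in the sources used here, and the values show a mean of 150 on each array after trimming 2% at each end. The signals were used as deposited, on the log2 scale with no pseudocount, and signals of 0 were raised to 0.1. A log2 fold change of 1 is a doubling of these scaled signals.

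Probe sets were named from the platform annotation, and symbols were compared with a RefSeq table of the mouse genome through Entrez identifiers. Of all probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. Of those with 1 symbol, 34741 matched and 0 symbols changed. No gene was named from a probe set with several symbols. A probe set counted as detected when called Present on at least 2 of the 4 arrays, which held for 26285. Each gene was represented by its detected probe set with the highest mean log2 signal, which gave 13148 genes of 18193. Where a probe set was Absent on both arrays of 1 group, the fold between means of log2 signals is written "at least".

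The comparison was splenectomized against intact mice, with no covariate, in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with an intensity trend). P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a median of 3.05 from the prior. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 32 lists, and again with an estimated correlation and with fry. With the estimated correlation camera uses the 2 residual degrees of freedom, so few lists could pass whatever the correlation of their members. The lists had 536 members, of which 446 were tested. Members were also adjusted over their list alone. A list score is the mean over members of the log2 signal minus the gene's mean over the 4 arrays. Errors are SD of 2 arrays unless named otherwise. Exact permutation of the 4 arrays has 6 assignments, so scores and detection calls are given as values.

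The lists, tests, thresholds and the rule for naming genes were set before the data were examined. The rule took 12 genes per direction by largest fold among those past the threshold, filled by smallest unadjusted p where fewer passed. It added up to 2 members of each list where none passed, a fixed set of immune genes (Ifng, Fas, Fasl, Nos2, Arg1, Tnf, Cd8a, Cd68, Prf1 and Gzmb), and the sex-linked genes. Names without an approved-style symbol were skipped in the first part. Lcn2, S100a8, C1s1, Serping1, C3ar1, Entpd1 and Pdcd1 were named after their values were seen, because few members of their lists passed over the list alone. Ccl24, Cd163 and Mrc1 were named after their values were seen, as members of the alternative activation list that went lower with no overlap between the groups. The alternatives tried were other scalings, a pseudocount or floor of 6.1, other detection filters, no intensity trend, a replicate block, the mean of a gene's probe sets, no probe sets prone to cross-hybridization and leaving out each array.

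The fit was tested on simulated data of 13148 genes with 2 arrays per group. With each gene's own residual SD and 100 genes each changed 2-fold and 4-fold, 0 and 0 were recovered. Because none was recovered, 2 further runs were set, each with 50 genes at 2-fold, 4-fold, 8-fold and 16-fold. With the moderated SD, 18, 36, 41 and 46 were recovered, and 17 of 158 calls (10.8%) fell outside these changed genes. Those calls can include members of a set of 20 genes shifted by 0.8 in the same run. The 10.8% is thus not a rate of false calls. With each gene's own SD, 4, 20, 32 and 33 were recovered, and 0 of 89 calls fell outside the changed genes. With no change simulated, limma called 0 genes, and 4.56% and 5.78% had an unadjusted p under 0.05. A set of 20 genes shifted by 0.8 on the log2 scale had camera p of 1.23e-17, 6.11e-18 and 4.22e-17, and an unshifted set 0.0707, 0.213 and 0.0749. Genes were drawn independently in every run, so the runs cannot show how camera behaves on lists whose members vary together. On the arrays, 21447 probe sets were Present on all 4 and 15588 Absent on all 4, and the median Absent signal was 6.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.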

Results

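In tumour-bearing eyes taken on day 15, genes of cytotoxic lymphocytes had higher signals in splenectomized than in intact mice. Granzyme B (Gzmb), a protease of cytotoxic granules, had a signal of 258 ± 26.7 in intact and 1024 ± 9.90 in splenectomized mice (SD, n = 2 each), 3.98-fold higher. Lists of macrophage, interferon gamma response, antigen presentation and chemokine genes rose in the same direction, and a list of cell division genes fell. These calls are of gene lists tested with camera at a preset correlation between genes. No single gene passed the threshold in limma over all 13148 genes tested (smallest adjusted p = 0.158). No list passed in camera with an estimated correlation (smallest adjusted p = 0.134). That version rests on the few residual degrees of freedom of the fit. Its larger p-values thus do not by themselves show members that vary together. The correlation was estimated at -0.042, -0.033 and -0.017 for the cytotoxic, macrophage and interferon gamma lists, below the preset 0.01. Over the called lists it ranged from -0.107 (dendritic) to 0.985 (lens).

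The data are 4 Affymetrix expression arrays of total RNA from whole tumour-bearing eyes of C57BL/6 mice, 2 from intact and 2 from splenectomized animals. Each mouse had received 10000 luciferase-expressing E.G7-OVA cells in the anterior chamber, the fluid-filled space behind the cornea. E.G7-OVA is a mouse T lymphoma line that makes chicken ovalbumin as a model antigen, so T cell transcripts in these eyes can come from the tumour as well as from infiltrating cells. The labels call the arrays separate samples and name a mouse as the source of each eye, but do not number the animals. The p-values of limma for single genes measure the spread between these samples. Those of camera at the preset correlation compare the members of a list with the other genes. They rest also on the number of genes and on that correlation, not on the spread between samples alone. Of 45101 probe sets, the authors' detection calls were Present for 53.2% and 58.6% on the arrays of intact replicates 1 and 2, and for 56.2% and 56.9% on those of splenectomized replicates 1 and 2. Across genes, the log2 signals of any 2 arrays correlated with Pearson's r of 0.942 to 0.981, where genes are not independent replicates. The number of arrays limits the precision of every value given here.

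The comparison of splenectomized with intact mice asks how the transcripts of an intraocular tumour and its host eye differ when the spleen was removed before the tumour cells were injected. The title of the series places it in work on the spontaneous elimination of intraocular tumours, interferon gamma, Fas ligand and macrophages. At an unadjusted p under 0.05, 1180 genes differed, 876 higher and 304 lower in splenectomized mice, where 657 would be reached by chance. The other pairings of the arrays gave 33 and 1131 genes. A count near 1180 was thus not particular to the comparison of splenectomized with intact mice. The intact and splenectomized groups did not overlap for 41.4% of genes, where chance gives 33.3%. Over all 26285 detected probe sets, named or not, 0 passed (smallest adjusted p = 0.134) and 2120 had an unadjusted p under 0.05. The median log2 fold change of all genes was 0.05. That median was -0.04 and 0.10 without intact replicate 1 or 2, and 0.02 and 0.08 without splenectomized replicate 1 or 2. Such fits leave 1 array in a group and take their spread from the other pair alone. The intact pair differed more (SD of the difference between arrays 0.745) than the splenectomized pair (0.408). Counts of genes from these fits are therefore not compared.

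Cytotoxic lymphocyte genes rose as a list. All 20 tested members had higher signals in splenectomized mice, 16 passed when adjusted over the list alone and 0 over all genes. Their median log2 fold change was 1.59, with quartiles of 1.32 and 2.02 (camera, adjusted p = 2.98e-20, and adjusted p = 0.134 with an estimated correlation). Ccl5, a chemokine released by activated T cells, was at 900.4 ± 45.9 in intact and 3096 ± 116 in splenectomized mice, 3.44-fold higher. The natural killer receptor genes Klrd1 and Klrc1 were 3.51-fold and 5.38-fold higher, and the granule protein gene Nkg7 was 4.25-fold higher. Ifng, which encodes interferon gamma, was at 133 ± 23.6 and 398 ± 23.8, 3.01-fold higher (adjusted p = 0.158). Perforin (Prf1) was 2.18-fold higher, with an adjusted p of 0.357. Cd8a, a coreceptor of cytotoxic T cells, was called Absent on both intact and Present on both splenectomized arrays, and its signal was at least 2.57-fold higher in the latter (adjusted p = 0.257).

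**Figure D1:**
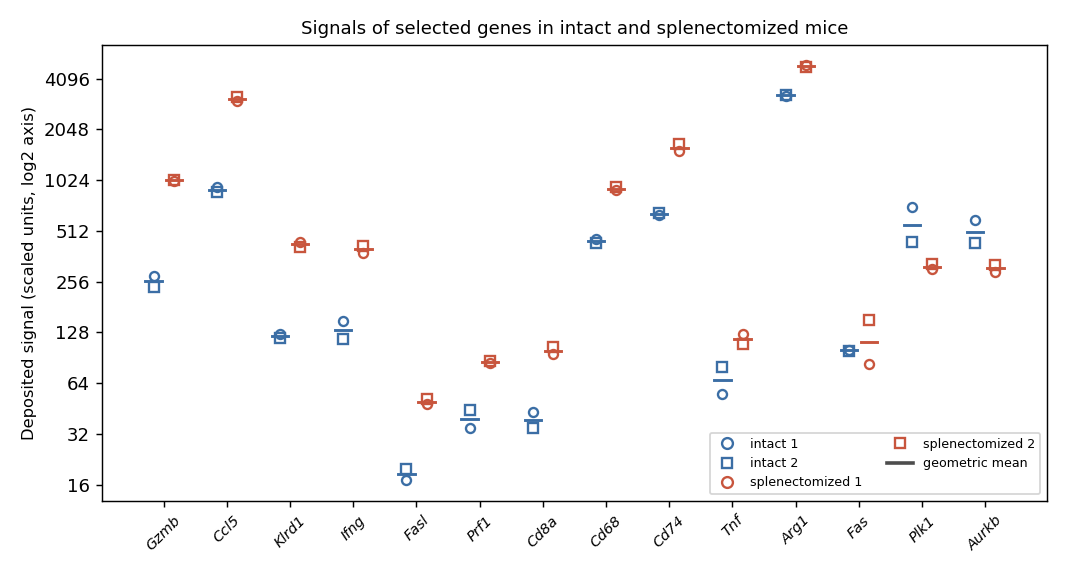
Deposited signal of 14 genes on each of the 4 arrays, on a log2 axis. Circles are replicate 1, squares replicate 2, and bars the geometric mean of each group (n = 2). Gzmb lies at 277 and 239 in intact and at 1017 and 1031 in splenectomized mice, while Fas overlaps between the groups.

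Genes shared by all T cells did not move with the cytotoxic genes. The pan T list, which the injected lymphoma also expresses, had a median log2 fold change of -0.15 over 14 members, of which 10 were lower (camera, adjusted p = 0.334). Its mean was 0.05, of the opposite sign to its median. Its adhesion receptor gene Cd2 passed when adjusted over the list alone, at 3.45-fold higher, and 0 passed over all genes. Zap70, a kinase of the T cell receptor pathway, was at 423 ± 110 in intact and 297 ± 48.0 in splenectomized mice (adjusted p = 0.624). Without intact replicate 2 the pan T median was -0.38 and called lower (adjusted p of camera 0.00166), and without intact replicate 1 it was 0.07 and called higher (adjusted p 0.02). The cytotoxic score minus the pan T score, each the mean log2 signal relative to the gene means, was -0.80 ± 0.50 in intact and 0.80 ± 0.13 in splenectomized mice. The list of CD4 helper and regulatory T cell genes had a median log2 fold change of 0.32 over 8 members (camera, adjusted p = 0.0781). Of these, 0 passed over the list alone or over all genes. Its Icos, a costimulatory receptor gene, was at 86.2 ± 6.72 in intact and 174 ± 35.1 in splenectomized mice. Without intact replicate 1 the list would be called higher (adjusted p of camera 0.0198).

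The T cell checkpoint list rose, with a median log2 fold change of 0.69 over 7 members (camera, adjusted p = 0.029, and adjusted p = 0.301 with an estimated correlation). When adjusted over the list alone 5 members passed, and 0 over all genes, and these did not all go the same way. Cd274, which encodes the checkpoint ligand PD-L1, was at 263 ± 20.5 in intact and 644 ± 67.0 in splenectomized mice. Havcr2, Ctla4 and Entpd1 were also higher, at 2.45-fold, 1.97-fold and 1.62-fold. Pdcd1, which encodes the receptor PD-1, was lower, at 1382 ± 169 in intact and 929 ± 141 in splenectomized mice. Without intact replicate 2 the call of this list was lost, at a median of 0.52 (adjusted p = 0.289).

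Macrophage and monocyte genes rose as a list. All 21 tested members had higher signals in splenectomized mice, 16 passed when adjusted over the list alone and 0 over all genes. The median log2 fold change was 0.87, with quartiles of 0.60 and 1.04 (camera, adjusted p = 1.28e-18, and adjusted p = 0.134 with an estimated correlation). Mpeg1, a pore-forming protein of phagocytes, was at 1298 ± 8.56 in intact and 2755 ± 79.7 in splenectomized mice. Cd68, a lysosomal membrane protein of macrophages, was at 446 ± 14.6 and 914 ± 28.3, 2.05-fold higher (adjusted p = 0.158).

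Genes of classical, inflammatory macrophage activation rose, with a median log2 fold change of 0.96 (camera, adjusted p = 1.6e-09, and adjusted p = 0.299 with an estimated correlation). All 14 tested members were higher, 9 passed over the list alone and 0 over all genes. Ptgs2, the inducible cyclooxygenase, was 2.74-fold higher, and Acod1, which makes itaconate, 2.96-fold. Tnf was at 67.8 ± 17.7 in intact and 118 ± 11.2 in splenectomized mice (adjusted p = 0.512). Nos2, the inducible nitric oxide synthase, was called Absent on all 4 arrays and was not tested. Genes of alternative activation did not pass (median log2 fold change 0.13 over 15 members, 8 higher and 7 lower, camera adjusted p = 0.701), and 0 members passed over the list alone or over all genes. Of these, Arg1, which encodes arginase, was at 3269 ± 29.9 in intact and 4867 ± 55.2 in splenectomized mice, 1.49-fold higher (adjusted p = 0.342). Stab1, a scavenger receptor gene, was 1.95-fold higher. Among the lower members, the scavenger receptor gene Cd163 and the mannose receptor gene Mrc1 were 1.51-fold and 1.34-fold lower. The chemokine gene Ccl24, Present on both intact and Absent on both splenectomized arrays, was at 136 ± 24.0 in intact and 34.0 ± 31.0 in splenectomized mice (adjusted p = 0.492). The list's median was -0.15 without intact replicate 1 and -0.10 without splenectomized replicate 1. The classical activation score minus the macrophage score was -0.08 ± 0.33 in intact and 0.08 ± 0.03 in splenectomized mice, a difference of 0.16 that is smaller than the SD of the intact pair. The alternative activation score minus the macrophage score was 0.42 ± 0.35 in intact and -0.42 ± 0.25 in splenectomized mice, a difference of -0.84. The classical minus the alternative score was -0.50 ± 0.68 and 0.50 ± 0.29, a difference of 0.99. In both, the groups did not overlap, and the differences were not tested.

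Interferon gamma response genes rose as a list. All 25 tested members were higher, 14 passed over the list alone and 0 over all genes. The median log2 fold change was 0.84 (camera, adjusted p = 2.16e-14, and adjusted p = 0.134 with an estimated correlation). The transcription factor gene Irf8 was at 242 ± 1.27 in intact and 507 ± 6.51 in splenectomized mice, and the guanylate-binding protein gene Gbp6 was 2.29-fold higher. The interferon gamma score minus the macrophage score was 0.08 ± 0.08 in intact and -0.08 ± 0.01 in splenectomized mice. The list thus did not rise more than the macrophage list, and the difference of -0.16 was not tested. Type I interferon response genes rose as well, with a median of 0.66 over 20 members, all higher (camera, adjusted p = 3.43e-13, and adjusted p = 0.299 with an estimated correlation). Of these, 12 passed over the list alone and 0 over all genes. The antiviral genes Rsad2 and Xaf1 were 2.59-fold and 2.10-fold higher.

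Antigen presentation genes rose, with a median log2 fold change of 0.66 over 11 members, all higher and with no overlap between the groups (camera, adjusted p = 7.6e-11, and adjusted p = 0.299 with an estimated correlation). Over the list alone 7 passed and over all genes 0. Cd74, the invariant chain of MHC class II, was at 647 ± 13.4 in intact and 1598 ± 108 in splenectomized mice, and the class II gene H2-Ab1 was 2.27-fold higher.

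Chemokine and chemokine receptor genes rose, with 17 of 18 members higher and a median log2 fold change of 0.76 (camera, adjusted p = 3.08e-10, and adjusted p = 0.299 with an estimated correlation). Over the list alone 10 passed and over all genes 0. Ccl3 and Ccl4, which attract monocytes and lymphocytes, were 3.16-fold and 2.83-fold higher. Complement genes rose, with all 10 members higher and a median of 0.71 (camera, adjusted p = 1.42e-06, and adjusted p = 0.299 with an estimated correlation). Of these, Cfb, C1ra, C1s1, Serping1 and C3ar1 passed over the list alone and 0 over all genes. Cfb, complement factor B, was 2.56-fold higher. Neutrophil genes rose, with 10 of 11 members higher and a median of 0.62 (camera, adjusted p = 0.000276, and adjusted p = 0.335 with an estimated correlation). Mmp8, Il1r2, Lcn2 and S100a8 passed over the list alone and 0 over all genes, and the list's call was lost without intact replicate 2, at a median of 0.26 (adjusted p = 0.133).

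The Fas and death receptor list rose by a small amount, with a median log2 fold change of 0.21 and 11 of 16 members higher (camera, adjusted p = 0.0406, and adjusted p = 0.301 with an estimated correlation). Fasl, Tnfrsf1a and Tnfrsf1b passed over the list alone and 0 over all genes. Fas ligand (Fasl), the death ligand of cytotoxic cells, was at 18.5 ± 1.98 in intact and 49.9 ± 2.33 in splenectomized mice, 2.70-fold higher (adjusted p = 0.332). The tumour necrosis factor receptor genes Tnfrsf1a and Tnfrsf1b were 1.57-fold and 1.95-fold higher. Fas, the receptor of Fas ligand, was at 100.2 ± 0.919 and 117 ± 48.0, with overlapping groups (adjusted p = 0.861), and its log2 fold change of 0.16 turned to -0.27 without splenectomized replicate 2. The list's call was lost without intact replicate 2, at a median of 0.38 (adjusted p = 0.309), and without splenectomized replicate 2, at 0.19 (adjusted p = 0.215). Without splenectomized replicate 1 the median was 0.44.

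B cell and plasma cell genes rose, with 7 of 10 members higher and a median of 0.61 (camera, adjusted p = 0.029, and adjusted p = 0.301 with an estimated correlation). Jchain, which joins secreted immunoglobulin A and M, was at 22.4 ± 8.27 in intact and 134 ± 47.3 in splenectomized mice and alone passed over the list, with 0 over all genes. Ms4a1, which encodes CD20, was 3.40-fold higher at low signals. Igha, the heavy chain of immunoglobulin A, was at 48.4 ± 18.9 and 542 ± 67.1, 11.6-fold higher (adjusted p = 0.158). Dendritic cell genes rose, with a median of 0.43 over 8 members (camera, adjusted p = 0.0289, and adjusted p = 0.301 with an estimated correlation). Fscn1, an actin-bundling protein of mature dendritic cells, alone passed over the list, at 1.61-fold higher, and 0 passed over all genes, while Cd83 was at 109 ± 0.636 in intact and 164 ± 9.69 in splenectomized mice. Without intact replicate 2 both lists lost their calls, at medians of 0.89 for the B cell and 0.41 for the dendritic list (adjusted p = 0.21 and 0.358). The dendritic list also lost its call without splenectomized replicate 2, at 0.45 (adjusted p = 0.0865). The B cell median was 0.18 without intact replicate 1 and 0.36 without splenectomized replicate 1.

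Lysosome and phagocytosis genes rose, with all 15 members higher and a median of 0.56 (camera, adjusted p = 6.37e-08, and adjusted p = 0.299 with an estimated correlation). Over the list alone 6 passed and over all genes 0. The protease gene Ctsk was 1.64-fold and the scavenger receptor gene Cd36 2.39-fold higher. Fibroblast and extracellular matrix genes rose, with 18 of 19 members higher and a median of 0.62 (camera, adjusted p = 4.78e-10, and adjusted p = 0.299 with an estimated correlation). Over the list alone 6 passed and over all genes 0. The collagen genes Col1a1 and Col6a1 were 1.94-fold and 1.87-fold higher. Endothelial genes rose, with a median of 0.30 over 13 members (camera, adjusted p = 0.0113, and adjusted p = 0.299 with an estimated correlation). Eng alone passed over the list, at 1.85-fold higher, with 0 over all genes, and Plvap was 1.43-fold higher. Hypoxia and glycolysis genes rose, with a median of 0.22 over 17 members, 0 of which passed over the list alone or over all genes (camera, adjusted p = 0.0289, and adjusted p = 0.487 with an estimated correlation). The glucose transporter gene Slc2a1 was 1.45-fold and Bnip3 1.26-fold higher. The endothelial call was lost without intact replicate 2, at a median of 0.48 (adjusted p = 0.161), and the median was 0.18 without splenectomized replicate 1. The hypoxia call was lost without intact replicate 2, at 0.15 (adjusted p = 0.356), and without splenectomized replicate 1, at 0.12 (adjusted p = 0.213).

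Cell division genes fell as a list, the only 1 of the 32 lists called lower. All 24 tested members had lower signals in splenectomized mice, 0 passed over the list alone or over all genes, and the median log2 fold change was -0.49, with quartiles of -0.57 and -0.40. The adjusted p was 1.64e-11 with camera and 0.412 with an estimated correlation. Plk1, a kinase of mitosis, was at 575 ± 191 in intact and 315 ± 14.4 in splenectomized mice, and Aurkb, another mitotic kinase, at 513 ± 114 and 308 ± 20.6. The proliferation scores were 0.25 ± 0.36 in intact and -0.25 ± 0.09 in splenectomized mice, and 0.50 on intact replicate 1. The median was -0.24 without intact replicate 1 and -0.73 without intact replicate 2, and the list was called lower in both. Intact replicate 1, which had the highest score, was also the array with the lowest ocular signals. The proliferation score minus the pan T score was 0.28 ± 0.05 in intact and -0.28 ± 0.02 in splenectomized mice, a difference of -0.55 that was not tested.

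Ocular genes separated 1 array from the rest, not the groups. The mean score of the rod, cone, inner retina, Muller glia, lens and pigment lists was -1.23 on intact replicate 1 and 0.65 on intact replicate 2, against 0.57 and 0.01 on splenectomized replicates 1 and 2. Rod photoreceptor genes had a median log2 fold change of 0.60 over 19 members (camera, adjusted p = 0.0738), cone genes 0.49 over 8 (adjusted p = 0.187), inner retina genes 0.57 over 16 (adjusted p = 0.142) and pigment genes 0.47 over 14 (adjusted p = 0.142). For the rod gene Pdc, signals were 666 and 3266 in the intact pair and 3556 and 2070 in the splenectomized pair. Abca4, Pde6c, Gng13, Slc17a6 and Mlana varied likewise, while the cone gene Gngt2 was at 101 and 77.1 in the intact and 116 and 124 in the splenectomized pair. Crystallin and other lens genes rose with camera, with a median of 0.68 over 18 members (adjusted p = 0.00709, and adjusted p = 0.68 with an estimated correlation), as did Muller glia genes, with 0.59 over 11 (adjusted p = 0.0296, and adjusted p = 0.68 with an estimated correlation). Without intact replicate 1 the medians of both turned to -0.08, called lower for the lens list (adjusted p = 0.0357) and not called for the Muller list (adjusted p = 0.142), and without intact replicate 2 they were 1.53 for lens and 1.497 for Muller genes. The lens crystallin genes Crygs and Cryba1 had intact values of 4976 ± 2441 and 4190 ± 2454. In the Muller list Apoe, which macrophages also express, was at 1478 ± 488 and 2569 ± 60.6, and Slc1a3 at 79.5 ± 53.1 and 131 ± 4.81. In the pigment list Mitf was at 89.4 ± 32.5 and 121 ± 17.2. Without intact replicate 1 the rod, cone, inner retina and pigment medians were -0.53, -0.38, -0.28 and -0.60, and without intact replicate 2 they were 1.87, 1.296, 1.65 and 1.52. Camera called these lists lower in the first case, except the cone list (adjusted p = 0.0804), and higher in the second. It also called them higher without splenectomized replicate 2, with adjusted p from 0.00197 to 0.0431. In these 6 lists 0 members passed over their list alone or over all genes.

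**Figure D2:**
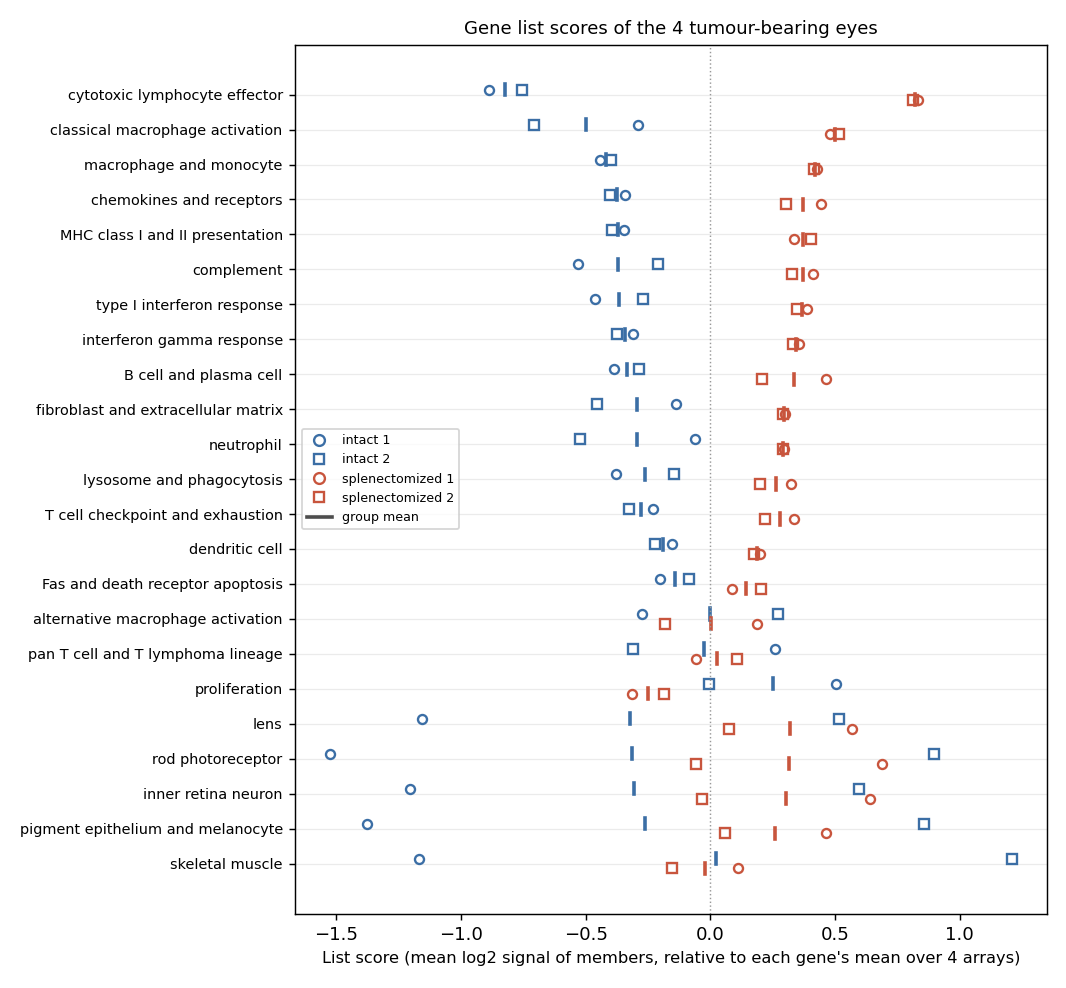
Scores of 23 gene lists on each of the 4 arrays, as the mean log2 signal of the members relative to each gene's mean over the arrays. Circles are replicate 1, squares replicate 2, and bars group means (n = 2). The cytotoxic scores are -0.89 and -0.76 in intact and 0.83 and 0.81 in splenectomized mice, while in the rod list intact replicate 1 lies apart at -1.53.

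The remaining tissue lists were not called. Surface epithelium genes had a median log2 fold change of 0.30 over 17 members (camera, adjusted p = 0.0866). The cornified envelope gene Sprr1a, at 479 ± 112 in intact and 1098 ± 182 in splenectomized mice, passed over the list alone, with 0 over all genes, and the keratin gene Krt13 was 1.64-fold higher. Adipose genes had a median of 0.18 over 5 members (adjusted p = 0.334), of which Fabp4, a fatty acid binding protein, passed over the list alone at 2.17-fold higher, with 0 over all genes, and Adipoq was at 13.1 and 7.15. With each array left out in turn, the adipose median ranged from 0.03 to 0.52. Skeletal muscle genes had a median of 0.03 and a mean of -0.04 over 14 members (adjusted p = 0.486), and erythroid and blood genes a median of 0.39 over 4 (adjusted p = 0.169). In both, 0 members passed over the list alone or over all genes. Ckm, the muscle creatine kinase, was at 238 ± 49.7 and 183 ± 1.27, and Myh4, a fast myosin, at 185 on intact replicate 2 and between 11.7 and 32.6 on the other arrays. Leaving out intact replicate 1 turned the surface epithelium and muscle medians to -0.22 and -1.07 (camera, adjusted p = 0.0249 and 8.01e-16), and leaving out intact replicate 2 gave 0.85 and 0.99 (adjusted p = 4.42e-06 and 0.000154). Without splenectomized replicate 2 the surface epithelium list was also called higher (adjusted p = 0.0223). The erythroid list was called higher without intact replicate 1 (adjusted p = 0.000507). The haemoglobin gene Hbb-b2 and the platelet gene Itga2b were 1.42-fold and 1.36-fold higher.

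Both sexes were used, and the labels do not give the sex of each animal. The Y-linked genes Eif2s3y, Kdm5d and Uty were called Present on all 4 arrays, and the X-inactivation transcript Xist on 3. Eif2s3y was at 138 and 209 in the intact and 300 and 274 in the splenectomized pair, and Xist between 6.3 and 21.3. Camera called the 4 sex-linked genes higher (adjusted p = 0.0392, and adjusted p = 0.562 with an estimated correlation), with 0 past over the list alone or over all genes. The list joins Xist with Y-linked genes, so a shared direction cannot tell the sex of the animals. The median log2 fold change was 0.74. The call was lost without intact replicate 1, at 0.31 (adjusted p = 0.214), and without splenectomized replicate 1, at 0.54 (adjusted p = 0.0671), and without intact replicate 2 the median was 1.38.

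None of the genes with the smallest p-values passed. On the higher side, beside Gzmb, Ccl5, Ccl3, Klrd1, Igha, Cd74, Klrc1 and Nkg7, these were Blvrb, Lce3a, Hcar2 and Ccrl2, each at an adjusted p of 0.158. Blvrb, a biliverdin reductase, was at 207 ± 3.04 in intact and 579 ± 15.3 in splenectomized mice. Lce3a, a protein of the cornified envelope of skin, was 4.29-fold higher, the niacin receptor gene Hcar2 2.88-fold and the chemokine receptor-like gene Ccrl2 3.25-fold. On the lower side, Lrmp, a membrane protein of lymphoid cells, was at 945 ± 13.6 and 561 ± 5.16, 1.69-fold lower (adjusted p = 0.2). The mitosis genes Hmmr, Kif20a, Spdl1 and Ncapg were 1.72-fold, 1.66-fold, 1.75-fold and 1.70-fold lower, with adjusted p between 0.333 and 0.402. Fubp1, Dnajc11, Bad, Dclk3, Ankrd40 and Yme1l1 were between 1.41-fold and 1.75-fold lower. For Fubp1, Dnajc11, Bad, Hmmr and Yme1l1, other detected probe sets of the gene went the opposite way. Cep131, a centrosome gene, was called Present on both intact and Absent on both splenectomized arrays, and was at least 2.52-fold lower in the latter (adjusted p = 0.35).

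Present calls on both splenectomized and Absent calls on both intact arrays were found for 384 probe sets, and the opposite for 340. The other pairings of the 4 arrays gave 510 and 148, and 610 and 245.

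With 2 arrays per group, an exact permutation test of a single value cannot go below p = 0.333, two-sided. Of the 32 lists, 21 passed with camera, and the other pairings of the 4 arrays gave 14 and 12. Their smallest unadjusted p of camera was 3.1e-13 (skeletal muscle list) and 3.18e-15 (rod list), against 9.32e-22 for the cytotoxic list here. Only the cytotoxic, macrophage and interferon gamma lists had a smaller p than both. A small p of camera was thus not particular to the comparison of splenectomized with intact mice. With fry, a rotation test, 6 lists passed: cytotoxic, macrophage, interferon gamma response, antigen presentation, chemokines and dendritic cells (smallest adjusted p = 0.00444).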

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

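The ocular covariate and the crossed replicate block were chosen after seeing the data, and the other alternatives before. Of the 21 called lists, 11 kept their direction and call in all 14 planned settings other than the set tests: the cytotoxic, macrophage, classical activation, interferon gamma, type I interferon, antigen presentation, chemokine, complement, fibroblast, proliferation and lysosome lists. With all 4 arrays kept, calls were lost for the dendritic list with quantile normalization or the mean of probe sets and for the hypoxia list with median centring, the mean of probe sets or no cross-hybridizing probe sets. The Fas list lost its call with no detection filter, the B cell list with Present calls on all 4 arrays and the sex-linked list with the mean of probe sets. Calls were gained for the rod list with quantile normalization or median centring and for the CD4 list with Present calls on all 4 arrays. The other calls lost in these 14 settings came from leaving out an array, and the ocular covariate ended the call of the Muller list and gave 23 lists, gaining rod and skeletal muscle as lower and erythroid as higher. With an estimated correlation 0 lists passed, and with fry 6. Counting Marginal calls as Present was planned but not run, since the calls hold 0 Marginal values.

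Limma called 0 genes and 0 probe sets with median centring, a pseudocount, a floor, other detection filters, no trend or the mean of probe sets. Quantile normalization called 1 gene, Ccl5 (adjusted p = 0.0472, against 0.103 to 0.457 as the smallest in the other planned settings with all 4 arrays), and 1 probe set. With the ocular score as a covariate 656 genes and 899 probe sets passed. The score comes from the same arrays and differs most within the intact pair (-1.23 and 0.65). As a covariate it takes up that spread and leaves fewer residual degrees of freedom. These counts are therefore not read as a result, and the cause was not tested. Leaving out 1 array gave from 0 to 2830 genes and from 0 to 3574 probe sets, where the lone array is assumed to vary like the other group.

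Arrays with the same replicate number deviated in opposite ways (correlation of deviations -0.443), and the labels give no pairing. The replicate block called 0 genes (546 at an unadjusted p under 0.05, by limma), 0 probe sets and 25 lists (gaining rod, inner retina, surface epithelium and pigment), and the crossed block 99 genes, 358 probe sets and 21 lists, 18 of them among those called without a block. The crossed block joins arrays that deviated in the same way, so it too takes up spread within the groups. With the replicate block the alternative activation median stayed 0.13 while the direction given by camera reversed.

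Medians of lists not called with no covariate reversed elsewhere. The ocular covariate gave -0.073 for alternative activation, -0.11 for rod, -0.0098 for cone, -0.068 for surface epithelium and -0.13 for pigment genes, and -0.030 for Abca4. Quantile normalization gave -0.011 for alternative activation. For pan T the median stayed below 0, at -0.031 with the ocular covariate and -0.15 with fry, and the direction given by the tests turned from lower to higher. The cause was not tested for these.

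With each array left out in turn, medians ranged from -0.38 to 0.068 for pan T, -0.15 to 0.38 for alternative activation, 0.26 to 0.55 for erythroid, -0.53 to 1.87 for rod, -0.38 to 1.296 for cone, -0.28 to 1.65 for inner retina, -0.079 to 1.497 for Muller, -0.085 to 1.53 for lens, -0.22 to 0.85 for surface epithelium, -0.60 to 1.52 for pigment and -1.07 to 0.99 for muscle lists. For proliferation, which kept its call, they ranged from -0.73 to -0.24. Single genes ranged from -0.27 to 2.03 for Pdc, -0.48 to 1.81 for Abca4, -0.15 to 2.05 for Pde6c, -0.19 to 2.02 for Gng13, -0.29 to 3.07 for Slc17a6, -0.22 to 1.85 for Mlana, -3.21 to 0.77 for Myh4, -0.27 to 0.59 for Fas and -0.27 to 1.49 for Xist. The cause was not tested. Over all named genes and settings, 1182 results were the same, 180 went past the threshold and 10 reversed. For lists, by the direction the test gives, these counts were 442, 23 and 22, and 57 calls were lost. Signals of probe sets called Absent, with a median of 6.1, limit what can be read from dim genes.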

Other observations

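The tests in this part were chosen after the result was seen. A list of 47 genes of cornification, the hardening of the outermost skin cells, was put together after several of its members were seen to be higher, so its values are given with no test of the list. Of its 26 tested members, 26 were higher in splenectomized mice, with a median log2 fold change of 1.72, and limma called 0 over all genes. Keratin genes of differentiated epidermis were among the highest, with Krt1 8.47-fold (30.0 ± 15.8 in intact and 253 ± 132 in splenectomized mice) and Krt10 4.61-fold higher, and the late-stage genes Krtdap 5.81-fold and Sbsn 3.12-fold. Genes of basal stratified epithelium did not share this, with a median of 0.20 over 9 members, of which 0 passed. Relative to intact replicate 2 alone, their median was -0.19. Krt5 and Krt14, keratins of basal cells, were 1.02-fold and 1.34-fold higher.

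Immunoglobulin A probe sets were also among the highest. The 3 probe sets of Igha were 11.6-fold, 8.14-fold and 8.54-fold higher in splenectomized mice in limma (adjusted p = 0.151, 0.134 and 0.134). This was not particular to immunoglobulin A. Probe sets with several symbols of the kappa light chain were 8.34-fold, 9.12-fold and 8.37-fold higher, and a dim one of Igk 1.79-fold. The probe sets of Ighm, the heavy chain of immunoglobulin M, went both ways. Most were higher, up to 5.63-fold, while the brightest were at 0.668-fold and 0.713-fold.

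Ocular signals were low on intact replicate 1. Scaling of the array is argued against, since its ocular score stayed at -1.12 after median centring. Less ocular tissue in that sample stays open: the muscle list was lower and the pan T and proliferation lists higher there than on the other arrays, but these 3 lists were chosen with their scores known. RNA degradation stays open, since 1 of 2 control transcripts had its highest 3' to 5' ratio there.

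Immune lists were higher in splenectomized mice. Less ocular tissue in intact replicate 1 is argued against as the whole cause, since the cytotoxic and macrophage scores of the splenectomized mice exceeded intact replicate 2 by at least 0.82. Scaling is argued against by a cytotoxic median of at least 1.53 under 2 other scalings. The cytotoxic and macrophage shifts differed by 0.80. This bears on a lower share of tumour cells alone only if that would shift both lists equally, which was not tested, so it stays open. The 4 arrays have 3 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many as 21 lists (highest other 14). An effect of surgery on the cells in the eye may explain the pattern, as an untested hypothesis.

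Cornification genes were higher in splenectomized mice. The median was 1.57 over the 16 members Present on all 4 arrays. Since the list was made after several members were seen to be higher, this cannot decide on noise of dim probe sets. Relative to intact replicate 2 the members had a median of 1.91, which for the same reason cannot decide on less ocular surface in intact replicate 1. Eyelid skin in the splenectomized samples could be a source and stays open: of 15 hair follicle keratin genes, 4 were Present on any array, and 0 were Present on both splenectomized and Absent on both intact arrays. A response of the ocular surface to surgery stays open as well, as an untested hypothesis.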
